A study of Homo sapiens with 7 samples.

How the data were processed

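RNA sequencing of 4 bone-metastatic (BoM) and 3 lung-metastatic (LuM) subpopulations of A549 cells was analysed from the table the authors deposited. Per the labels' protocols, libraries were made from total RNA after poly(A) selection or removal of ribosomal RNA, without a statement of which was used for which sample, and were amplified by PCR without molecular identifiers being mentioned. Per the submitters' processing notes, cutadapt 1.9.1, HISAT2 2.0.1 and HTSeq 0.6.1 were used with the genome build GRCh37. Their settings, and whether counting used strand, are not given in the sources used here. Per the file headers, the values are FPKM, which the authors deposited with 2 decimals. How FPKM was derived from the fragments is not given in the sources used here. The authors' deposited table also holds a fold change, its log2 and a p-value for BoM against LuM. Their test and any adjustment for multiple testing are not given in the sources used here. Every gene in the table has a deposited p-value under 0.05 and a fold change of at least 1.5, so it is a selection made on these samples. For 914 of 984 genes above 1 FPKM in a group, the log2 fold change in the authors' deposited table was smaller in size than the log2 ratio of mean FPKM (median size 0.733 against 0.934), so it was not taken directly from these FPKM values. The sign was the same for all 1396 genes.

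FPKM values are not counts, so no count-based test was run. The plan fixed before the data were examined foresaw this case: genes with at least 1 FPKM in at least 3 libraries (909 genes) were tested on log2(FPKM + 1) with limma 3.58.1 (R 4.3.3), with a trended and robust prior, no covariate, 2-sided, and Benjamini-Hochberg adjustment over the genes tested at an adjusted p under 0.05. Differences are on the log2(FPKM + 1) scale, which understates the change of low genes. On simulated values for these 909 genes, with 200 changed genes in each of 20 runs, 49.2% of 2-fold and 92.0% of 4-fold changes were recovered, and 3.8% of the calls were false. The simulated noise was independent between genes and the genes were not selected on the groups. Both differ from these data, so these rates need not hold for the real test. Gene lists (28, fixed beforehand) with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry. Since all genes in the table were selected, camera compares a list with other selected genes and not with the transcriptome. Group separation was tested by exact permutation over the 35 splits of 7 libraries into 4 and 3, on 1 minus Spearman's correlation.

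Genes were named by a rule fixed beforehand. Per direction it took up to 12 genes past the threshold with a mean of at least 1 FPKM and no overlap between the groups, filled to 5 by the smallest unadjusted p where fewer than 5 genes passed in that direction, then 3 more by adjusted p. From each list it took up to 4 members past the threshold or, where none passed, the 2 tested members with the highest mean. Genes with clone or LOC names were skipped in the first parts. The rule gave 44 genes, of which a few, with the list counts that rest on them, are not described here. Other list members are named as such after their values were seen.

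Depth was recovered from 18 genes with transcripts under 400 bases, as the library size between 12 M and 24 M (M for 1000 times 1000) fragments at which FPKM times length gave whole fragments. 66 of 66 values with up to 8 fragments lay within 0.1 of a whole number. These settings were chosen after seeing the data. All 7 libraries held odd fragment numbers, which rules out smaller sizes by a factor of 2, and larger multiples fit as well by construction. With a range of 4 M to 40 M the best fit moved in 3 libraries, to 7.9 M in LuM 1, 33.9 M in BoM 2 and 34.6 M in BoM 4. With genes under 250 bases, 3 values were left in BoM 3, and it moved to 12.7 M at a mean distance of 0.164 from a whole number, or to 8.5 M at 0.002 in the wider range, where LuM 1 again moved to 7.9 M. The lower sizes leave out genes at 0.5 fragments or less. At about 17 M fragments, 1 fragment in a gene of 100 bases is already over 0.5 FPKM, so short genes move in steps. The SEs given for them come from limma's spread between libraries and do not model counting error. GC content and length were taken from the longest transcript in GENCODE release 29, matched by gene identifier for 1355 genes (97.1%), with no coordinates used because that annotation is on another build. Tests of direction within 20 classes of GC content used the exact conditional distribution with directions shuffled within classes. On simulated directions of these 1355 genes without a leaning, 3.6% of 1050 tests fell under the 0.05 threshold, and 100.0% of 50 planted leanings did. A planted leaning multiplied the chance of each gene of a chromosome to be higher by 0.5, which is a large effect. Simulated directions were independent between genes, as the test assumes. Real directions may depend on each other, so these rates need not hold for them. Other calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

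Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter on low values, the replicate number as a block, leaving out each library, the other list tests, and 2 other distances (Pearson's correlation, and Euclidean distance over the 500 most variable genes). Leaving out BoM 3 and BoM 4 together, removing the GC trend (per library, the median deviation in 10 classes of GC content) with and without the block, protein-coding genes only, and all tests of GC content, chromosomes and GO terms were added after seeing the data. The class medians were taken over genes selected as differing between the groups. Removing them therefore also takes out part of the contrast of BoM with LuM, whatever its cause.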

Results

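RNA was sequenced from 7 subpopulations of A549, an established human lung adenocarcinoma cell line, obtained through a mouse model in which these cells spread to several organs. 4 subpopulations came from bone metastases (BoM 1 to 4) and 3 from lung metastases (LuM 1 to 3), and LuM served as the control group. The table analysed here holds the FPKM values (fragments per kilobase of transcript, scaled to library size) of genes that the authors had listed as differing between these same 7 libraries. Genes outside that list were not analysed here. Library totals were not part of the table. The depth recovered from the FPKM steps of short genes, where multiples fit as well, lay between 15.8 M (M for 1000 times 1000) fragments in LuM 1 and 17.6 M in LuM 2 and BoM 1. The labels do not say that each library came from its own animal or culture, so p-values measure only the spread between these samples, which may be technical.

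The comparison asks which genes differ in A549 cells between subpopulations that colonised bone and subpopulations that colonised lung. In the authors' deposited table, 845 genes were listed higher in BoM and 551 lower, each with a p-value under 0.05 and a fold change of at least 1.5. The median fold change in the authors' deposited table was 1.69 and the largest 3.88. There, 147 genes reached a fold change of at least 2, of which 98 were higher and 49 lower in BoM. The FPKM values of the groups did not overlap for 503 of these genes (36.0%), with all BoM values above all LuM values for 272 genes and below them for 231. Chance gives 5.71% for genes that were not selected on the groups. Every direction and test given here concerns genes chosen because BoM and LuM differed, so no share among them is a genome-wide share.

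Refitted with limma on log2(FPKM + 1), 4 of the 909 genes with enough signal passed an adjusted p under 0.05, 3 of them higher and 1 lower in BoM, and all 4 differed by at least 2-fold on that scale. The 909 genes had been selected on these same libraries, so these adjusted p-values do not bound the share of false calls. An adjustment over all expressed genes was not possible. RNU6-1161P (ENSG00000251985, chromosome 22), a copy of the U6 small nuclear RNA, was at 8.36, 6.35, 4.64 and 3.96 FPKM in BoM 1 to 4 and at 0, 1.66 and 1.12 in LuM 1 to 3 (limma adjusted p = 0.0116). MIR4258 (ENSG00000264349, chromosome 1), a microRNA gene, was at 2.50, 1.30, 2.60 and 2.54 FPKM in BoM 1 to 4 and was listed at 0 in all 3 LuM libraries (limma adjusted p = 0.000494). The microRNA gene MIR339 (ENSG00000199023, chromosome 7) was listed at 0 in all 4 BoM libraries and was at 4.03, 1.81 and 3.05 FPKM in LuM 1 to 3 (limma adjusted p = 8.68e-05). AL592188.3 (ENSG00000263806) is an unnamed locus that the naming rule skips and that was named after its values were seen. It is listed on the sequence GL000220.1 and not on a numbered chromosome. AL592188.3 was at 2.19, 2.27, 5.30 and 2.22 FPKM in BoM and at 0.81, 0 and 0 in LuM (limma adjusted p = 0.0113). These values rest on few fragments, at the recovered depth an estimated 2 to 4 per BoM library for MIR4258, 3 to 6 per LuM library for MIR339 and 7 to 15 per BoM library for RNU6-1161P. A group listed at 0 throughout shows no spread. The limma p-values and SEs of MIR4258 and MIR339 may therefore understate counting error. U6 copies are nearly identical, so the locus behind the RNU6-1161P fragments is uncertain. The annotated transcripts of MIR4258 and MIR339 are 91 and 94 bases long. Whether their fragments came from these genes or from overlapping transcripts was not tested, so a difference in the microRNAs themselves was not shown. The other tested genes did not pass, although 300 of the 909 (33.0%) had an unadjusted p under 0.05, 168 higher and 132 lower. RNU6-1161P did not pass without LuM 1 (adjusted p = 0.198) or LuM 3 (adjusted p = 0.057), with a pseudocount of 0.1 or 5 or without the filter on low values, and its adjusted p ranged from 9.48e-05 to 0.405 over all alternatives. AL592188.3 did not pass without LuM 2 or LuM 3, with a pseudocount of 5 or without that filter. MIR339, at 0 in BoM, falls under the filter whenever a LuM library is left out and was not tested there. With a GC trend removed from each library, none of the 3 genes with a known GC content passed. The correction was chosen after seeing the data and also takes out the listed contrast typical of each GC class. The log2 difference went from 1.67 ± 0.235 (SE) to 2.63 ± 0.361 for MIR4258 (adjusted p = 0.0648), from -1.95 ± 0.231 to -0.99 ± 0.275 for MIR339 (adjusted p = 0.187) and from 1.9 ± 0.362 to 1.58 ± 0.390 for RNU6-1161P (adjusted p = 0.18). SEs were larger there and the moderated variance had about 8 degrees of freedom in place of 18.5. For MIR4258 the difference grew along with its SE, so the larger SE alone did not end its call. With fewer degrees of freedom its unadjusted limma p rose from 1.09e-06 to 7.28e-05. MIR339 also differed by less. Over all alternatives the adjusted p ranged from 1.62e-06 to 0.351 for MIR4258 and from 1.46e-08 to 0.45 for MIR339. The count was 267 without BoM 1, 135 without BoM 2, 2 without LuM 1 and 1 without LuM 3, and 0 among protein-coding genes alone, of which 277 had an unadjusted p under 0.05.

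Levels from here on are mean FPKM ± SD over n = 4 BoM and n = 3 LuM libraries, and none of the genes named below passed the adjusted threshold with all 7 libraries and no block or, where too low, was tested. With the replicate number as a block, FST (adjusted p = 0.000976), RNU2-27P (adjusted p = 0.00617) and UPK3B (adjusted p = 0.0493) passed, with adjusted p of 0.000248 to 0.45, 0.00563 to 0.351 and 0.000298 to 0.54 over the other alternatives. Of all genes named by the rule, 16 that had not passed did so without BoM 1, 20 without BoM 2 and 1, RNU2-27P, without BoM 4. Among genes with higher values in BoM, the smallest unadjusted p-values belonged to BST2, an interferon-induced membrane protein that tethers virus particles, at 1.24 ± 0.417 in BoM and 0.243 ± 0.0404 in LuM, and to the non-coding RNAs CASC19 (4.72 ± 1.81 and 1.43 ± 0.410) and LINC00346 (1.56 ± 0.827 and 0.307 ± 0.116). For each of these 3 genes all BoM values lay above all LuM values. IGFBP1, a secreted binding protein of insulin-like growth factors, was at 23.8 ± 10.5 in BoM and 7.04 ± 4.43 in LuM, a log2 difference of 1.67 ± 0.488 (SE). HRH1, the histamine H1 receptor, was at 3.06 ± 1.5 and 0.907 ± 0.282. DLG5-AS1 was at 1.35 ± 0.320 and 0.403 ± 0.0611. It is antisense to DLG5, and without strand information their reads cannot be told apart.

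Among genes with lower values in BoM, UPK3B, a uroplakin-family membrane protein, was at 25 ± 26.5 in BoM and 81.5 ± 39.8 in LuM. PAFAH1B3, a catalytic subunit of a platelet-activating factor acetylhydrolase, was at 53.8 ± 27.4 in BoM and 128 ± 26.7 in LuM, a log2 difference of -1.38 ± 0.435 (SE). CTXN1 was at 8.31 ± 3.56 and 21.7 ± 7.17, PDZD4 at 1.18 ± 0.315 and 4.10 ± 2.62, and the chondroitin sulfotransferase CHST13 at 0.700 ± 0.217 and 2.07 ± 0.539. In these last 4 genes all BoM values lay below all LuM values. The log2 difference of CHST13 was -0.85 ± 0.245 (SE) and turned to 0.11 when a GC trend was removed from each library, a correction chosen after seeing the data. GATSL2 (0.548 ± 0.542 and 2.11 ± 0.905) and the U2 small nuclear RNA copy RNU2-27P (0.613 ± 0.528 and 2.46 ± 1.33) complete the genes with the smallest unadjusted p-values.

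**Figure D1:**
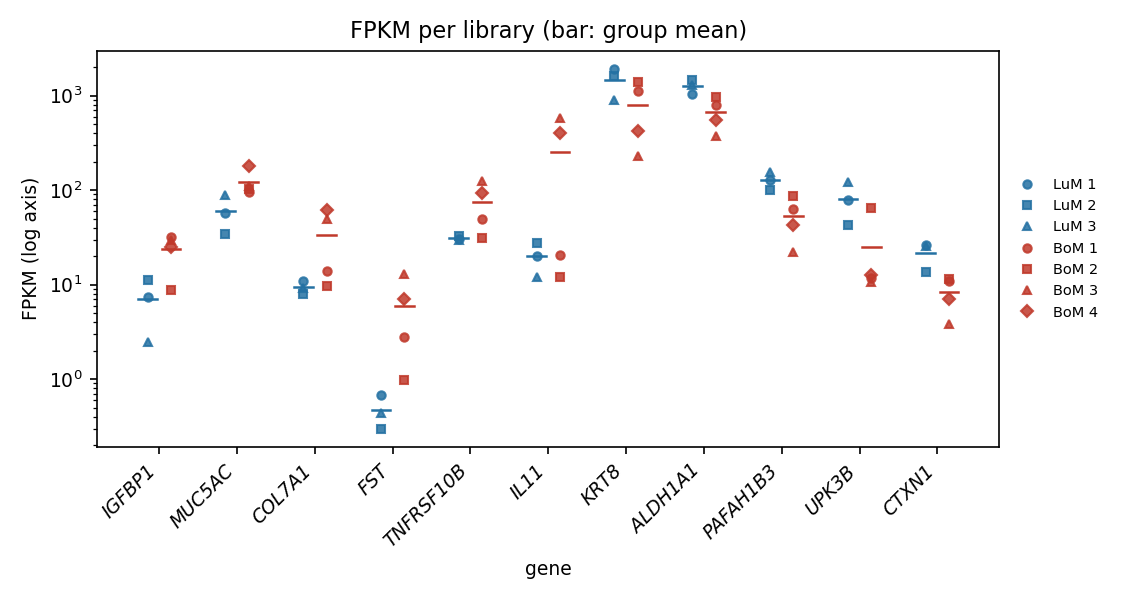
FPKM of 11 named genes (horizontal axis) on a log axis (vertical), with 1 point per library, LuM in blue and BoM in red, and a bar at each group mean. IL11 was at 573 and 400 FPKM in BoM 3 and BoM 4 and at 20.6 and 11.9 in BoM 1 and BoM 2, which lie within or below the LuM range of 12.2 to 27.4.

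Of 8 epithelial genes in the authors' deposited table, 6 were listed lower in BoM. KRT8 and KRT18, the keratin pair of simple epithelia, were at 792 ± 555 and 800 ± 396 in BoM against 1478 ± 522 and 1364 ± 636 in LuM. Without BoM 3 and BoM 4, an analysis chosen after seeing the data, the log2 difference went from -1.17 to -0.17 for KRT8 and from -0.79 to -0.19 for KRT18, and the list median from -0.807 to -0.354. KRT8 and KRT18 have many processed pseudogenes that can share reads with them. JUP, the junction protein plakoglobin, was at 45 ± 12.7 against 94.5 ± 29.5. The exceptions were CLDN1, a tight junction claudin at 56.6 ± 35.1 against 23.6 ± 9.48, and KRT19. The list as a whole did not pass the camera test against the other listed genes (adjusted p = 0.0581, or adjusted p = 0.398 with an estimated correlation), and 0 of 6 tested members passed, whether adjusted over all genes or adjusted over the list alone. 3 had an unadjusted p under 0.05. The median GC content of its members was 56.1%. JUP, CLDN1 and KRT19 are named as list members after their values were seen, as are the other members outside the naming rule below.

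Among the mesenchymal genes listed higher in the authors' deposited table, TNC, the matrix glycoprotein tenascin C, was at 11.4 ± 10.6 in BoM and 1.85 ± 1.03 in LuM, and AXL, a receptor tyrosine kinase, at 169 ± 83.0 and 87.1 ± 24.4. S100A4 was listed lower, at 369 ± 104 in BoM and 591 ± 146 in LuM. SNAI2 and ZEB2 stayed under 1.1 FPKM in every library. TNC, AXL and S100A4 did not pass over all genes or adjusted over the list alone. In BoM 3 and BoM 4, which stood apart from the other libraries, AXL was at 233 and 247, while BoM 1 and BoM 2 were at 111 and 85.3, within the LuM range.

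All 8 listed p53 targets were higher in BoM in the authors' deposited table. They were TNFRSF10B, a death receptor for TRAIL, TRIAP1, MDM2, the ubiquitin ligase of p53, ZMAT3, RRM2B, BTG2, EDA2R and SPATA18. TNFRSF10B was at 74.7 ± 42.6 in BoM and 30.8 ± 1.55 in LuM, TRIAP1 at 40 ± 21.1 and 22.2 ± 4.00, and MDM2 at 10.4 ± 3.93 and 6.01 ± 2.07. Without BoM 3 and BoM 4 the log2 difference went from 1.06 to 0.34 for TNFRSF10B and from 0.71 to 0.16 for TRIAP1, and the list median from 0.71 to 0.209. The list did not pass camera (adjusted p = 0.0581, or adjusted p = 0.454 with an estimated correlation). None of 7 tested members passed over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05. The median GC content of the 8 genes was 43.9%. Of the 28 lists fixed before the data were examined, these 2, epithelial genes and p53 targets, had enough tested members for camera, and 0 passed, with 0 unadjusted p-values under 0.05. By fry, the epithelial list had an unadjusted p of 0.0498 and an adjusted p of 0.0997, and the p53 list an adjusted p of 0.137. Without LuM 2 both lists passed camera (adjusted p = 0.0439), and over all alternatives the adjusted p ranged from 0.0143 to 0.398 for epithelial genes and from 0.0439 to 0.567 for p53 targets.

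TGF-beta targets listed higher in the authors' deposited table included ANGPTL4 (15.3 ± 8.56 in BoM and 5.34 ± 0.344 in LuM) and IL11, neither past the threshold over all genes. IL11, a cytokine that promotes osteoclast formation, was also the listed member of the osteolytic and bone-colonisation list, at 251 ± 281 and 19.9 ± 7.62. Its log2 difference of 2.17 ± 1.57 (SE) rested on BoM 3 and BoM 4, and without these libraries it was -0.25, an analysis chosen after seeing the data. Extracellular proteases and inhibitors listed higher in the authors' deposited table included SERPINE2 (5.10 ± 0.868 and 2.75 ± 1.55), the membrane-bound metalloproteinase MMP14 (1.38 ± 0.498 and 0.647 ± 0.283) and CST6. SERPINE2 and MMP14 did not pass over all genes. Of the extracellular matrix genes, 3 were listed higher and 1 lower. COL7A1, the collagen of anchoring fibrils, was at 33.7 ± 25.9 in BoM and 9.38 ± 1.46 in LuM, EFEMP1 at 2.48 ± 0.625 and 1.16 ± 0.671, and THBS1, the matrix protein thrombospondin 1, at 6.39 ± 2.02 and 12.7 ± 4.66. All 4 of them, TNC included, passed adjusted over the list alone and 0 over all genes. Since the table was selected on these samples, a pass over a list alone is not independent evidence.

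Among cholesterol and lipid synthesis genes listed lower in the authors' deposited table, FADS2, a fatty acid desaturase, was at 34.1 ± 21.9 in BoM and 59.7 ± 9.40 in LuM, and LSS, lanosterol synthase, at 9.33 ± 3.25 and 15 ± 2.10. Neither passed over all genes. Both listed NRF2 targets were lower, TKT, the transketolase of the pentose phosphate pathway, at 218 ± 102 and 341 ± 26.3, and HMOX1, haem oxygenase 1, at 17.1 ± 3.44 and 29.7 ± 17.7. Neither of the 2 passed on either scale, and the log2 difference of HMOX1, -0.61 ± 0.419 (SE), turned to 0.06 with the GC trend removed. In the stem-like and drug-tolerance list, ALDH1A1, a retinal dehydrogenase, was at 673 ± 259 in BoM and 1266 ± 221 in LuM with no overlap between the groups, and LGR5, also the listed member of the WNT list, stayed under 0.1 FPKM. ALDH1A1 passed adjusted over its list alone, as its 1 tested member, and not over all genes.

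BMP and ID genes went both ways, with 2 listed higher and 3 lower in the authors' deposited table. FST, the activin antagonist follistatin, was at 5.92 ± 5.30 in BoM and 0.473 ± 0.192 in LuM with no overlap between the groups, BMPER stayed under 1.3 FPKM, and SMAD6, an inhibitor of BMP signalling, was at 19.2 ± 12.6 and 30.4 ± 2.34. The log2 difference of SMAD6, -0.84 ± 0.441 (SE), turned to 0.07 with the GC trend removed. 1 of 3 tested members, FST, passed adjusted over the list alone and 0 over all genes, although FST did so without BoM 2 (adjusted p = 0.000248) and with the replicate block. Of the Notch genes, LFNG, a glycosyltransferase that modifies Notch, was listed lower (3.27 ± 1.23 and 6.71 ± 3.36), and it passed adjusted over its list of 1 and not over all genes. Its log2 difference, -0.81 ± 0.386 (SE), turned to 0.12 with the GC trend removed. The 2 listed YAP and TEAD targets were AXL and GADD45A, both listed higher and neither past the threshold on either scale. GADD45A, a stress-induced growth arrest gene, was at 227 and 128 FPKM in BoM 3 and BoM 4 and between 7.69 and 14.4 in the other 5 libraries. Of the integrins and cadherins, 2 were in the table, both listed lower. ITGB5, at 68.6 ± 21.6 and 129 ± 60.4, was the 1 tested member and passed adjusted over its list alone and not over all genes, and CDH5 was near 0.

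Interferon-stimulated genes were listed higher in 3 of 3 cases in the authors' deposited table, BST2, IRF7 (2.84 ± 1.77 in BoM and 1.26 ± 0.222 in LuM) and IFI27, of which 1 of 2 tested passed adjusted over the list alone and 0 over all genes. Antigen presentation genes went both ways, with HLA-B (6.12 ± 4.10 and 2.31 ± 0.747) and CD74 listed higher and PSMB9 (6.19 ± 1.92 and 9.48 ± 2.70) lower, and 0 of 2 tested passed on either scale. HLA-B shares sequence with other HLA class I genes, so its level is uncertain. Of the alveolar and lung-lineage genes, the gel-forming mucin MUC5AC was listed higher (122 ± 37.6 and 60.4 ± 27.6, no overlap) and the pioneer factor FOXA1 lower (2.02 ± 0.669 and 3.31 ± 1.41), and 1 of 2 passed adjusted over the list alone and 0 over all genes. Single listed members were VEGFA in the hypoxia and glycolysis list (6.99 ± 3.48 and 3.82 ± 0.765), HERPUD1 in the stress response list (43.6 ± 26.2 and 23.4 ± 0.875, turning to a log2 difference of -0.08 without BoM 3 and BoM 4), and PHEX (osteoblast-like list) and IL1A (NF-kB-driven cytokine list), both under 1 FPKM in each library. VEGFA and HERPUD1 did not pass, and PHEX and IL1A were too low to be tested. Among markers of other cells, CD74 was the listed member of the osteoclast and myeloid list, at 0.233 ± 0.148 and 0.0400 ± 0.0361, and CDH5 that of the stromal and endothelial list, at 0.0350 ± 0.0507 and 0.163 ± 0.174. No member of 4 lists was in the authors' deposited table, namely proliferation genes, transcripts without a poly(A) tail, mitochondrially encoded genes and cytosolic ribosomal protein genes. The list of transcripts without a poly(A) tail holds 26 fixed names and leaves out the small nuclear RNA copies described above. Its absence therefore does not show that such RNAs were alike in BoM and LuM. Which samples had poly(A) selection is not stated, and an effect of library preparation on those copies was not tested. Over all lists, 59 genes were in the table, 44 were tested, 20 had an unadjusted p under 0.05 and 0 passed after adjustment by limma.

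The BoM libraries did not stand apart from LuM to the same degree. Over the tested genes, Spearman's correlation across genes lay between 0.940 and 0.958 within LuM. BoM 1 correlated with LuM libraries at 0.869 to 0.940, BoM 2 at 0.881 to 0.947 and BoM 3 at 0.552 to 0.668, while BoM 3 and BoM 4 correlated with each other at 0.938. Genes are not independent replicates. Genes listed higher in BoM lay at a median log2 distance from LuM of 0.17 in BoM 1, 0.43 in BoM 2, 1.28 in BoM 3 and 0.96 in BoM 4. For genes listed lower the distances were -0.47, -0.40, -1.12 and -0.74. Without BoM 3 and BoM 4, the log2 difference of 17 of 39 named genes reversed or was under 0.5 times that over all libraries. Besides those given above, it went from 1.37 to 0.29 for COL7A1, from 1.98 to 0.15 for GADD45A, from 0.84 to 0.20 for AXL, from 0.63 to 0.06 for VEGFA, from 0.65 to 0.10 for IRF7 and from 0.91 to 0.12 for HLA-B. For S100A4 it went from -0.69 to -0.33, for FADS2 from -1.04 to -0.16, for TKT from -0.78 to -0.16 and for SMAD6 from -0.84 to -0.18. The mean Spearman distance between groups exceeded that within groups by 0.0815. An exact one-sided permutation test over the 35 splits of the 7 libraries gave p = 0.0857, where the smallest possible p is 0.0286. A separation beyond the spread between libraries was therefore not shown, and so few splits give the test little resolution.

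**Figure D2:**
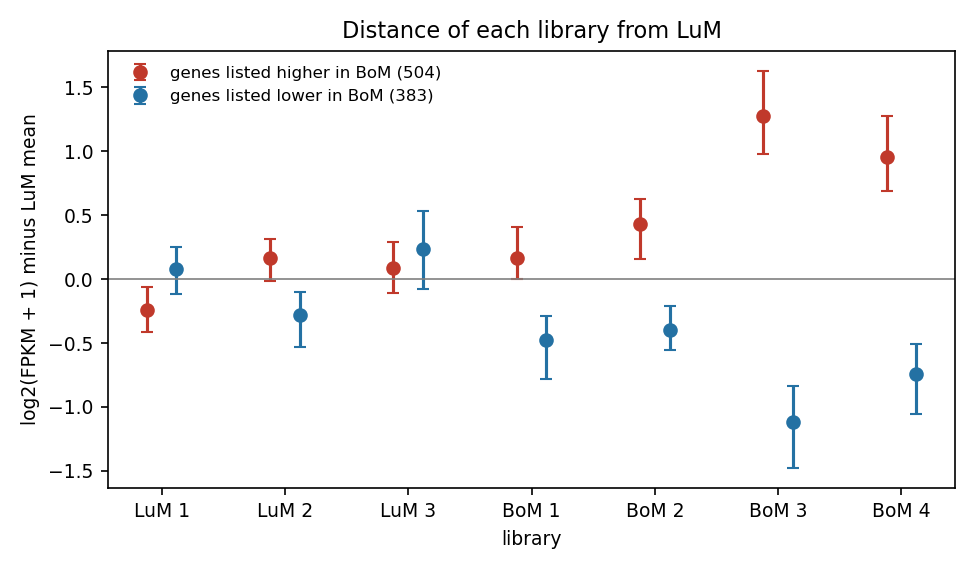
Median log2(FPKM + 1) minus the LuM mean (vertical axis) in each library (horizontal axis) for 504 genes listed higher in BoM (red) and 383 listed lower (blue), with bars from the lower to the upper quartile over genes and each LuM library set against the other LuM libraries. BoM 3 and BoM 4 lie at 1.28 and 0.96 for genes listed higher, and BoM 1 and BoM 2 at 0.17 and 0.43.

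The GC content of the listed genes differed by direction. Genes listed higher in BoM in the authors' deposited table had a median transcript GC content of 45.3% (817 genes with a transcript sequence), and genes listed lower one of 58.7% (538 genes), a gap of 13.4 percentage points (2-sided permutation test, p = 1e-05, the smallest that 100000 permutations can give). The shuffling treats genes as independent, while all directions come from 1 contrast of the same 7 libraries. Its p therefore does not measure the spread between samples. Of the 136 genes with the lowest GC content, 96.3% were listed higher, and of the 136 with the highest, 20.6%. Libraries within a group also differed along GC content. The difference between LuM 1 and LuM 2 correlated with GC content across 887 genes at a Spearman's rho of 0.63, and that between BoM 1 and BoM 3 at 0.54. With the GC trend removed from each library, an analysis chosen after seeing the data, 0 of the 890 tested genes with a known GC content passed limma's adjusted threshold and 162 had an unadjusted p under 0.05, and 74.4% of the 890 kept the direction of the authors' deposited table. AL592188.3 has no transcript sequence and was not among them. The GC classes differ in their share of genes listed higher, so this removal takes out part of the listed contrast by construction. The loss of calls and directions therefore does not tell a technical GC trend from a biological one.

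**Figure D3:**
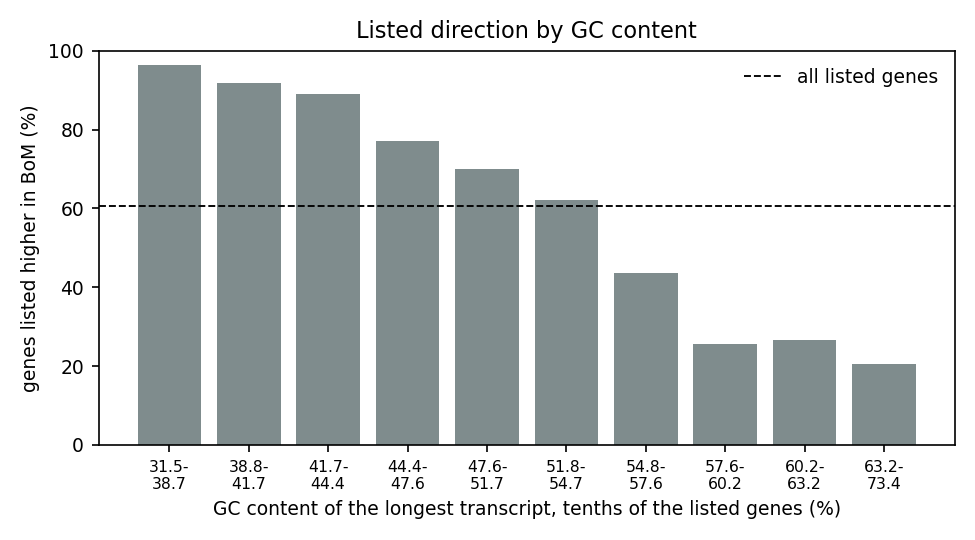
Share of genes listed higher in BoM (vertical axis, percent) in 10 classes of listed genes by GC content of the longest transcript (horizontal axis, percent), with a dashed line at 60.5%, the share among all listed genes. The share is 96.3% in the class with the lowest GC content and 20.6% in that with the highest.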

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

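All tests of explanations in this part were chosen after the result was seen, except those of non-coding RNA, transcript length and the count of lists over splits. With 77 items tested for a BoM library far from the other 3 of its group, chance gives about 3.9 flags, and 4 were found. UPK3B was at 64.6 FPKM in BoM 2 and at 10.7 to 12.7 in the other BoM libraries. BST2 was at 1.86 FPKM in BoM 4 and at 1.00 to 1.06 in the others. JUP was at 26.0 FPKM in BoM 3 and at 50.3 to 52.1 in the others. MIR4258 was at 1.30 FPKM in BoM 2, an estimated 2 fragments, and at 2.50 to 2.60 in the others, an estimated 4 fragments each.

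Other splits of the 7 libraries into 4 and 3 gave as many genes as the real one, so chance cannot be excluded for the gene counts. The 4 genes of the real split were reached by 8 of the 35 splits, the highest other count being 297. The count of genes higher in BoM (3) was reached by 6 splits (highest other 86), that of genes lower in BoM (1) by 9 (highest other 242) and that of genes with at least 2-fold difference (4) by 8 (highest other 173). For the lists, a count of 0 is reached by all 35 splits whatever the data (highest other 2), so the splits decide nothing there. A separation as large as 0.0815 occurred in 3 of the 35 splits, with a highest other value of 0.129, so chance cannot be excluded there either, although the genes were chosen on the real split. The splits that call many times the real count, 297 genes for BoM 2, 3 and 4 against the rest and 221 for BoM 1, 3 and 4 against the rest, point to a structure of the samples in which BoM 3 and BoM 4 stand apart.

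The contrast of BoM with LuM rested mostly on BoM 3 and BoM 4, with a median log2 distance from LuM in the listed direction of 1.21 and 0.86, against 0.31 in BoM 1 and 0.41 in BoM 2. A difference in sequencing depth is argued against by genes of at least 10 FPKM, which many fragments cover: BoM 3 differed from BoM 1 by a median log2 difference of 1.46 ± 0.105 (bootstrap SE) in genes listed higher and of 0.88 ± 0.057 the other way in genes listed lower, which library size cannot give in scaled values. A GC-related difference between libraries met its first criterion, as the GC slopes of BoM 1 and BoM 3 differed by 20.9 bootstrap SE over genes. As the whole cause it missed a criterion added after the values were seen. With the GC trend removed, the gap between these libraries went from 0.90 to 0.41 ± 0.032 (bootstrap SE over genes). That criterion cannot decide the question, because the genes, their listed directions and both libraries were chosen on these same values. Whether BoM 1 is a wrongly labelled LuM library cannot be told apart from a BoM library near LuM, because its mean correlation with LuM (0.901, against 0.940 as the lowest within LuM) is lowered by a gene choice that used its label. BoM 2 lay about as near to LuM, with correlations of 0.881 to 0.947, and the same limit holds for it. A biological difference between the BoM subpopulations stays open and untested.

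Genes listed higher in BoM had a lower GC content than genes listed lower, by 13.4 percentage points. A larger share of non-coding RNA in BoM is argued against, since the gap was 14.7 points among protein-coding genes. Transcript length is argued against, since the smallest gap in any of 5 classes of transcript length was 8.5 points. GC-dependent recovery of fragments in the libraries stays open and may contribute, since the difference between LuM 1 and LuM 2, which the gene choice treated alike, followed GC content with a rho of 0.63. Regulation of AT-rich and GC-rich genes that differs between subpopulations would give such differences too and was not tested.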

How the results depend on the processing

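Analyses without both BoM 3 and BoM 4, with the GC trend removed and with protein-coding genes only were added after seeing the data. The planned count-based tests, scalings of counts and count filters were not run, because the table holds FPKM. The main counts were 4 genes, 3 higher, 1 lower and 4 with at least 2-fold difference, with 0 lists. A pseudocount of 5 gave 2, 1, 1 and 0, because it shrinks low genes, and no filter on low values gave 2, 1, 1 and 2 over all genes of the table. A pseudocount of 0.1 gave 3 genes, all among the 4. Leaving out 1 library at a time gave 1 to 267 genes, 1 to 198 higher, 0 to 69 lower, 1 to 145 with at least 2-fold difference and 0 to 2 lists. The highest gene counts came without BoM 1 (267) and without BoM 2 (135), and 2, 3 and 1 genes passed without LuM 1, LuM 2 and LuM 3, where the filter leaves MIR339 untested, so its loss was fixed. Without BoM 3 the count was 4. Both lists passed together only without LuM 2. Without BoM 3 and BoM 4 together 2 genes passed, 1 of them higher and both with at least 2-fold difference. MIR4258 and AL592188.3 fall under the filter there and were not tested, so their loss was fixed. Without these libraries 2 named genes reversed, IL11 (-0.25) and HERPUD1 (-0.08), as their high values were in BoM 3 and BoM 4. Protein-coding genes alone gave 0 genes in each count, because none of the genes past the threshold is annotated in that class.

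With the GC trend removed, 0 of the 890 genes with a known GC content, which leaves out AL592188.3, passed in each count and direction, and 4 named genes reversed, CHST13 (0.11), HMOX1 (0.06), SMAD6 (0.07) and LFNG (0.12). These losses and reversals are partly built in, since the trend was estimated on genes selected as differing between the groups. With the replicate block as well, the counts were again 0, and the reversed genes were CHST13 (0.09), S100A4 (0.02), HMOX1 (0.06), SMAD6 (0.13), LFNG (0.11) and FADS2 (0.00). Apart from the construction named, the cause was not tested. The replicate block alone gave 9 genes, 6 higher, 3 lower and 9 with at least 2-fold difference, including the 4, FST, RNU2-27P and UPK3B, and 1 list (epithelial genes, adjusted p = 0.0143, with 0.0439 to 0.398 over the other alternatives). Its test pools the variance over all genes (1818 degrees of freedom). The block also takes BoM 4, which has no LuM partner, out of the differences, and without BoM 4 alone the count was 5. The labels do not say whether the numbers pair the samples. Deviations of same-numbered libraries correlated at 0.48, -0.21 and -0.03, and not every library correlated best with its own number. These deviations also hold the GC-related differences between libraries and the distance of BoM 3 and BoM 4, so they cannot decide on pairing. The p of the separation was 0.1 to 0.2 over the alternatives, but with the 10 or 15 splits left when libraries are dropped it cannot fall under 0.05. Without any 1 of the BoM libraries, the real split had the highest separation of the 10 splits (exact permutation test, p = 0.1). Without any 1 of the LuM libraries 2 of 15 splits were as large, and without BoM 3 and BoM 4 together 2 of 10. The GC gap was 12.3 with mean GC content over transcripts and 14.7 in protein-coding genes. At the recovered depth, 1 fragment moves the short RNA genes by a large share of their value.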

Other observations

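All tests in this part were added after seeing the data, and those of chromosome 19, copy number and p53 targets had their expected outcomes written before their results. Tests of direction treat genes as independent, while all directions come from the same contrast of the same libraries. Their p-values therefore do not measure the spread between samples. Of 116 GO terms with at least 15 listed genes, 3 leaned lower in BoM by Fisher's exact test over the table (adjusted p under 0.05). Carbohydrate metabolic process had 17 of 21 genes listed lower (Fisher's exact test, adjusted p = 0.00738). Examples, chosen after their values were seen, are SLC25A1, the mitochondrial citrate carrier, at 44.1 ± 20.5 FPKM (SD, n = 4) in BoM and 80.1 ± 20.5 (SD, n = 3) in LuM, GYS1, muscle glycogen synthase, at 10.5 ± 3.34 and 16.9 ± 2.75, IDH2, mitochondrial isocitrate dehydrogenase, at 22.1 ± 14.2 and 37.9 ± 6.47, and HS6ST1, a heparan sulfate sulfotransferase, at 10.2 ± 3.66 and 19.0 ± 4.16. SDC4, the proteoglycan syndecan 4, was listed the other way, at 25.4 ± 11.5 and 13.7 ± 1.21. Integral component of membrane (125 of 249 listed lower) and plasma membrane (101 of 194) were split nearly evenly. They leaned lower only against the whole table, in which 60.5% of genes were listed higher. With directions shuffled within classes of GC content, 0 of the 116 terms passed, 14 had an unadjusted p under 0.05, and the smallest adjusted p was 0.296.

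Of 21 chromosomes with at least 20 listed genes, 4 leaned to one direction by Fisher's exact test (adjusted p under 0.05). 34 of 138 genes of chromosome 19 were listed higher, 85 of 109 of chromosome 2, 53 of 64 of chromosome 8 and 28 of 66 of chromosome 7. Within classes of GC content, 1 chromosome passed, chromosome 19, with 31 genes listed higher where 46.4 were expected (exact test within classes, adjusted p = 0.00886). If genes are taken as independent, their GC content does not account for all of its leaning. For chromosomes 2, 7 and 8 GC content may be enough, with a smallest adjusted p of 0.301 within the classes. A copy-number difference on chromosome 19 could not be told from none: with the GC trend removed, 1 of the 4 BoM libraries (BoM 1) had the chromosome's genes lower than other listed genes by over 2 SE (-0.19 ± 0.083, bootstrap SE). The same direction in each library was not found, since BoM 3 was at 0.03 ± 0.065, but BoM 2, 3 and 4 all lay within 2 SE of no difference.

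A hypothesis that p53 target genes move together in BoM was set against the make-up of the table. The 8 of 8 listed members were higher where 6.8 were expected from their GC content, and as many arise by shuffling directions within GC classes with a probability of 0.244 (exact, 1-sided). The direction and GC content of the table alone may therefore give this pattern. Of 4 lists with at least 5 listed members, 0 leaned to one direction by Fisher's exact test after adjustment (smallest adjusted p = 0.102, for p53 targets, with an unadjusted p of 0.0255).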
